A study of Theobroma cacao with 72 samples.

How the data were processed

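Leaf RNA of cacao was measured by RNA sequencing in 72 libraries of the genotypes NA32 and SCA6, after sprays of Phytophthora megakarya zoospores or of distilled water. Per the labels' protocols, the plants were grafted, the inoculated plants stood in a block of their own, leaves at stage C were taken, and each replicate pooled 2 leaves from different plants. Stranded mRNA libraries were read as single reads of 100 nt on an Illumina HiSeq in rapid mode in 5 runs; the run of each library is not given in the sources used here, so no value within a run is given. Groups and replicate numbers come from the labels, with 4 libraries in each of 18 groups.

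The authors deposited raw counts of reads per gene for 24831 genes, whole numbers with no normalization, in a table of all libraries. Per the submitters' processing notes, the tools were Trimmomatic, HISAT2, bedtools, featureCounts and DESeq2; their versions, roles and settings, and the genome build, are not given in the sources used here. The authors also deposited a table of signal values for 19462 genes, the counts divided by 1 size factor per library, from 0.528 to 2.52; the ratio of both tables was constant within each library to 5.2e-15. The 5369 genes left out of that table had at most 70 counts over all libraries and the others at least 71. Every test used the raw counts, and the signal table served only to check what it holds. None of the gene IDs matched the 24957 entries of the reference gene table (0 matches), so 30 lists of pathway genes and cell type markers fixed before the data were examined could not be tested, and genes appear by ID. How reads of near-identical genes were split in counting is not given in the sources used here, and such genes are uncertain.

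Library totals ran from 7.72 to 44.6 M counts, M standing for counts in units of 1e+06, with quartiles of 14.9, 16.9 and 18.4 M, and the median library had a count for 18794.5 genes. Counts were analysed with edgeR 4.0.16 in R 4.3.3: TMM normalization, the filter filterByExpr with its default settings, and the quasi-likelihood test (glmQLFit and glmQLFTest), 2-sided, with 1 coefficient per group and no replicate block. Adjusted p-values are Benjamini-Hochberg over the genes tested in a comparison, and a gene was called at an adjusted p under 0.05. The median SE of a log2 fold change was 0.26 to 0.32 for the responses to inoculation. Levels are means ± SD of CPM, made here from the raw counts; log2 CPM used a prior count of 2. A fold against a group at 0 counts was taken against a floor of 3 counts over the group, and with 1 to 3 counts as the ratio of pooled counts with an exact 95% interval; floors and intervals cover counting error only. p-values measure the spread between pooled samples of 2 leaves.

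Each response was inoculated minus water in a genotype at a time point, fitted over the 16 libraries of that time. The genotype by treatment test was the response of SCA6 minus that of NA32 in the same fit. Genotypes were compared as SCA6 minus NA32 over the 32 water libraries, averaged with equal weight over 0, 6, 24 and 72 hai, over the 8 libraries of 48 hai, and over all 72 libraries as the 48 hai difference minus the mean difference in water. These comparisons, the naming rule and most alternatives were chosen before the data were examined. Chosen after seeing the data were the genotype difference in inoculated leaves, the changes with time in water and their difference between genotypes, the division of variance and the shifts of group means, the neighbour counts, and the alternatives that left out 2 libraries or added 2 surrogate variables.

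The genes named are those past the threshold with a mean of at least 1 log2 CPM over the fit and, for comparisons of 2 groups, no overlap between the groups (within each time for genotype in water); of these, the 2 IDs with the largest positive and the 2 with the largest negative log2 fold change are named. At 48 hai the rule was applied without the library whose genotype pattern opposed its label, as no gene passed with it. Tc04v2_g004020 and other genes set across all groups in the closing observations were named by this rule in the comparison of time points.

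The genotype score of a library used genes whose median log2 CPM over all other libraries differed by more than 5 between the labelled genotypes, 32 to 37 genes per library. Genes seen in a single genotype had a mean of at least 1 CPM in it and at most 3 counts over all libraries of the other, the 2 libraries of opposite pattern left aside. For the score, a gene's place between the NA32 median (0) and the SCA6 median (1), kept within 0 and 1, was averaged over these genes. The share of variance was taken over the 64 libraries of 0, 6, 24 and 72 hai and 18559 genes, with 100000 shuffles of treatment within genotype and time. Alternatives were DESeq2 size factors in edgeR, DESeq2 1.42.0, limma 3.58.1 (voom with quality weights), no filter beyond a total count above 0, a filter of 1 CPM in 4 libraries, a fold of at least 2, the replicate number as a block, all 72 libraries or only the 8 compared in the fit, the difference net of 0 hai, leaving out each library in turn, leaving out the 2 libraries, and 2 surrogate variables from sva 3.50.0. The tests were tried on simulated counts, drawn independently for each gene, with 200 genes changed by known folds before use. No pair of libraries in a group agreed within sampling noise, and none was merged.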

Results

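Leaf RNA of 2 genotypes of cacao (Theobroma cacao) was sequenced after the plants were sprayed with Phytophthora megakarya, an oomycete that causes black pod disease, or with distilled water. The genotypes were Nanay 32 (NA32) and Scavina 6 (SCA6), grafted on a common rootstock and kept under shade nets. The study set a resistant against a susceptible variety. The inoculum held 300000 zoospores, the swimming spores of the pathogen, per mL and was applied in 4 sprays. Leaves were taken at 0, 6, 24 and 72 h after inoculation (hai) in both treatments, and at 48 hai from inoculated plants only. The 72 libraries fell into 18 groups of 4, and each library came from 2 leaves of different plants pooled together. Raw counts covered 24831 genes. The libraries held between 7.72 and 44.6 M counts (M, counts in units of 1e+06), with a median of 16.9 M, and the gene with the highest count took 2.36% to 11.7% of a library. Genes appear by their IDs as the files give them, because the files do not pair the IDs with names and 0 of them matched the reference gene table; for the same reason no position or function is given.

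Genes with levels far apart between NA32 and SCA6 gave each library a genotype score, from 0 for the NA32 level to 1 for the SCA6 level. The scores of 70 libraries matched their labels: the NA32 libraries among them lay at or below 0.227 and the SCA6 libraries at or above 0.808. The library labelled NA32 water 6 hai replicate 3 scored 0.892, and the library labelled SCA6 inoculated 48 hai replicate 3 scored 0.0371. Genes seen in a single genotype, with at most 3 counts over all libraries of the other that matched their labels, gave the same split. The library labelled NA32 water 6 hai replicate 3 held 0 counts of the 11 genes found in NA32 alone and 511 counts over 13 of the 14 genes found in SCA6 alone. The library labelled SCA6 inoculated 48 hai replicate 3 held 0 counts of those 14 SCA6 genes and 593 counts over the 11 NA32 genes. Counts of 0 allowed a share of the labelled genotype of up to 0.628% and 0.461% in these libraries (3 counts, counting error only). All libraries entered the comparisons as labelled. For each comparison that includes the group of either library, the number of genes called by edgeR is also given without these 2 libraries. The library labelled NA32 water 6 hai replicate 3 also entered the fits of other comparisons and could affect their calls. These comparisons were the SCA6 response and change with time at 6 hai, and the changes in water after 6 hai and their differences between genotypes. They were not refitted without it.

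**Figure D1:**
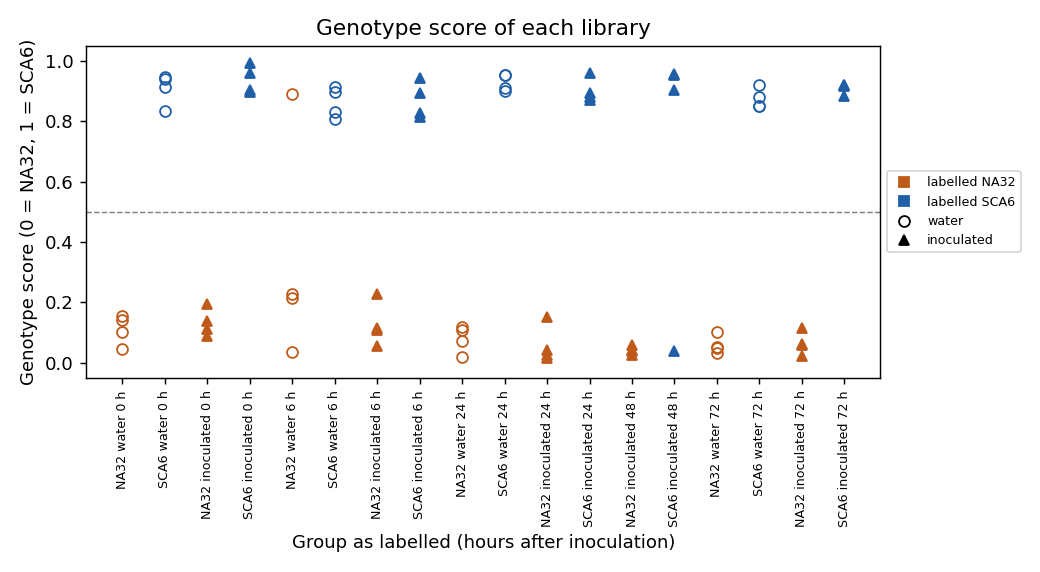
Genotype score of each of the 72 libraries (points), from 0 at the NA32 level to 1 at the SCA6 level, by labelled group along the horizontal axis; colour marks the labelled genotype and shape the treatment. The library labelled NA32 water 6 hai replicate 3 lies at 0.892 and the library labelled SCA6 inoculated 48 hai replicate 3 at 0.0371, each among the libraries of the other genotype.

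Time after spraying and genotype set apart more of the expression of these leaves than inoculation did. Over the 64 libraries of the time points with both treatments, time took 23.4% of the variance of log2 CPM (counts scaled to a library total of 1e+06), genotype 12.6% and their interaction 6.09%. Inoculation, within genotype and time, took 6.89%, against a median of 8.0% when the treatment labels were shuffled within genotype and time (permutation test, one-sided, p = 0.807). The other 51% lay between libraries of the same group. The first principal component held 32.6% of the variance, of which 52.7% lay within groups. Of component 2, 47.4% lay between genotypes, and of component 3, 56.2% lay between time points.

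**Figure D2:**
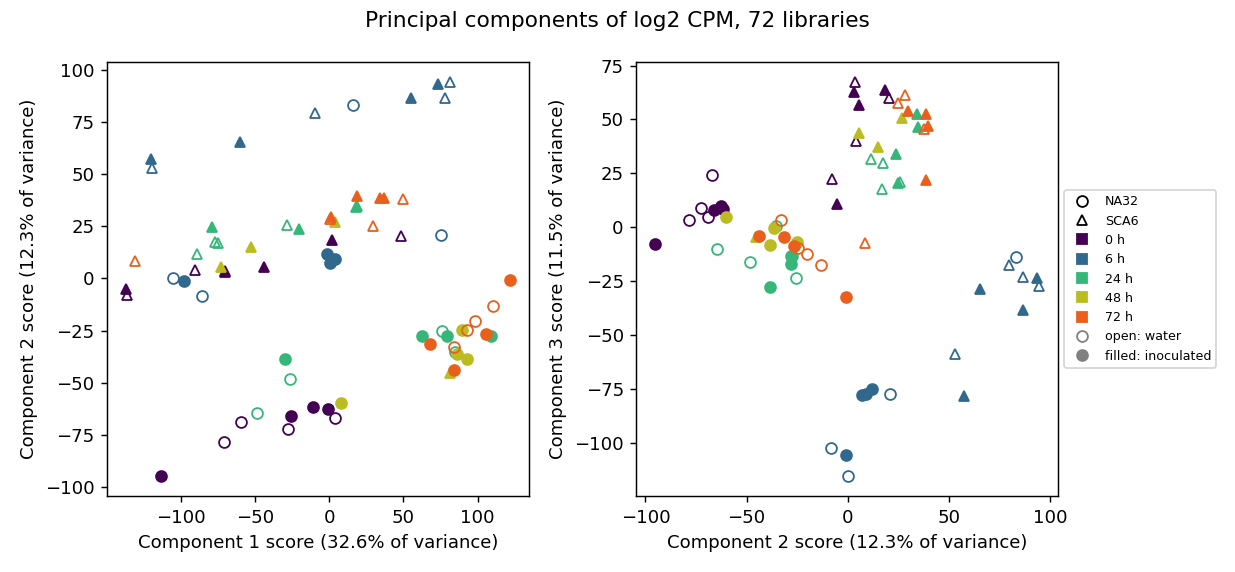
Scores of the 72 libraries on principal components 1 and 2 (left) and 2 and 3 (right) of log2 CPM; shape marks the labelled genotype, colour the time point and filling the treatment. Components 1, 2 and 3 held 32.6%, 12.3% and 11.5% of the variance, and water and inoculated libraries of a genotype and time point overlap.

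The first question of the design is which genes the inoculation changed in each genotype. The inoculated plants stood in a block of their own, so a difference between treatments cannot be told apart from one between blocks. In NA32, Tc03v2_g006740 was lower in inoculated than in water-sprayed leaves at 24 hai, and no other NA32 gene passed the test at 0, 6, 24 or 72 hai. Its level at 24 hai was 26.0 ± 1.80 CPM (SD, n = 4) in inoculated leaves and 58.3 ± 9.09 CPM (SD, n = 4) in water-sprayed leaves, and the highest inoculated library (28.3 CPM) lay below the lowest water library (47.2 CPM). The log2 fold change was -1.16 (SE 0.16), with an adjusted p of 0.0372 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In SCA6 at 24 hai the gene stood at 24.4 ± 3.10 CPM after inoculation and 46.3 ± 8.88 CPM after water (SD, n = 4 each), a log2 fold change of -0.91 that did not pass (adjusted p = 0.0725). Its level also moved with time in both genotypes: in water it was 159 ± 30.1 CPM in NA32 and 153 ± 30.3 CPM in SCA6 at 0 hai, and 8.48 ± 2.99 and 13.1 ± 5.18 CPM at 6 hai (SD, n = 4 each). The inoculated leaves of 0 hai stood at 144 ± 27.1 CPM in NA32 and 114 ± 30.6 CPM in SCA6 (SD, n = 4 each). The NA32 call was lost when any of the 8 libraries compared was left out, except replicate 1 of the water group. Over the 8 refits the log2 fold change lay between -1.26 and -1.08 and the adjusted p reached 0.364. It was also lost without the low-count filter (adjusted p = 0.0525), with the replicate number as a block (0.129), when only these 8 libraries were fitted (0.488) and net of the difference at 0 hai (adjusted p = 1, log2 fold change -1.02).

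**Figure D3:**
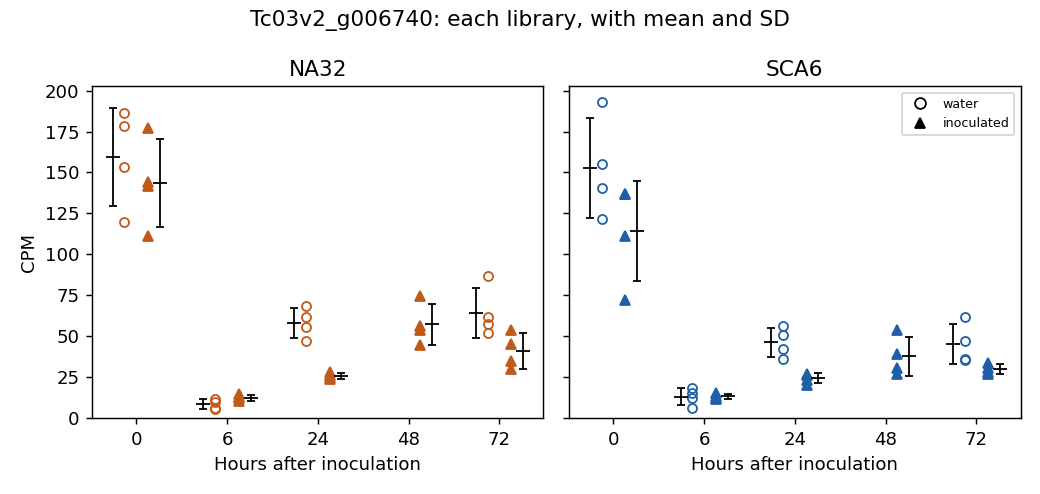
Level of Tc03v2_g006740 in CPM at each time point in NA32 (left) and SCA6 (right); points are libraries, bars the mean and SD of 4 libraries. At 24 hai the 4 inoculated NA32 libraries averaged 26.0 CPM and the 4 water libraries 58.3 CPM, and levels at 6 hai were below those at 0 hai in each group.

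In the other NA32 comparisons 0 genes passed with edgeR's quasi-likelihood test. The genes at an unadjusted p under 0.05 numbered 544 at 0 hai, 362 at 6 hai, 1059 at 24 hai and 394 at 72 hai, where 5% of the genes tested make 867 to 877. DESeq2 called 0, 5, 43 and 0 genes at these times, and limma voom 0, 0, 8 and 0. At 6 hai the count remained 0 without the library labelled NA32 water 6 hai replicate 3.

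In SCA6, no gene passed at 0, 6, 24 or 72 hai with edgeR's quasi-likelihood test, and the genes at an unadjusted p under 0.05 exceeded 5% of those tested at 24 and 72 hai. At 24 hai they numbered 2311 of 17374 genes (13.3%), with a smallest adjusted p of 0.0710, and other splits of the same 8 libraries gave up to 2431. At 72 hai they numbered 1992 of 17348 (11.5%), with a smallest adjusted p of 0.263, and other splits gave up to 2295. At 0 and 6 hai they numbered 439 and 311. Other tools made calls from the same counts: at 24 hai limma voom called 1299 genes and DESeq2 426, of which 384 were called by both, and at 72 hai limma voom called 0 and DESeq2 58. Both tools called 0 genes at 0 and 6 hai. At 24 hai edgeR called 76 genes without SCA6 water replicate 1 and 5 without SCA6 inoculated replicate 2. At 72 hai it called 1 gene without SCA6 water replicate 1 or replicate 4. On data simulated from the 24 hai libraries, the same test recovered 22% of 50 genes changed 2-fold and 94% of 50 changed 4-fold. The simulated genes varied independently of each other, unlike those of the real libraries, so these rates hold for such simulated counts only.

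The response itself did not differ between the genotypes past the threshold at any time. The genotype by treatment test of edgeR called 0 genes at 0, 6, 24 and 72 hai, and the genes at an unadjusted p under 0.05 numbered 562, 209, 1204 and 1072. DESeq2 called 0, 4, 18 and 6 genes, and limma voom 0, 0, 1 and 0. At 6 hai the edgeR count was also 0 without the library labelled NA32 water 6 hai replicate 3. Without NA32 water 24 hai replicate 1 the edgeR count at 24 hai was 2, and without SCA6 water 72 hai replicate 4 the count at 72 hai was 1.

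The counts of the 2 genotypes differed widely in leaves that had met no pathogen. Reads of both were counted over the same genes, and whether they were counted equally well in each genotype was not tested. A difference in counts between genotypes, here and below, thus need not be one in expression. In water-sprayed leaves, averaged over 0, 6, 24 and 72 hai, 3779 of 18038 genes differed, 2151 higher and 1628 lower in SCA6, and 1394 of them by at least 2-fold (783 higher, 611 lower). Tc07v2_g011290 stood at 19.8 ± 4.45 CPM in SCA6 and 1.29 ± 3.37 CPM in NA32, and its neighbour in ID order Tc07v2_g011300 at 39.6 ± 7.68 and 2.64 ± 6.11 CPM (SD, n = 16 each). In the other direction, Tc07v2_g004230 stood at 0.300 ± 0.299 CPM in SCA6 and 10.3 ± 4.84 CPM in NA32, and Tc07v2_g014400 at 3.52 ± 2.20 and 106 ± 47.8 CPM (SD, n = 16 each). Their log2 fold changes were 7.11 (SE 0.98), 4.41 (SE 0.48), -5.18 (SE 0.41) and -4.86 (SE 0.36), with adjusted p of at most 1.92e-05. The NA32 means include the library labelled NA32 water 6 hai replicate 3, without which the log2 fold changes of Tc07v2_g011290 and Tc07v2_g011300 were 8.05 and 5.14. That of Tc07v2_g011290 was 8.69 without NA32 water 72 hai replicate 5. Without the libraries whose score opposed their label the test called 4082 genes. As labelled, 9 genes higher and 22 lower in SCA6 met the naming rule, against 111 and 98 without the library labelled NA32 water 6 hai replicate 3. The genes named here were chosen with that library kept as NA32 and need not be those of largest difference.

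**Figure D4:**
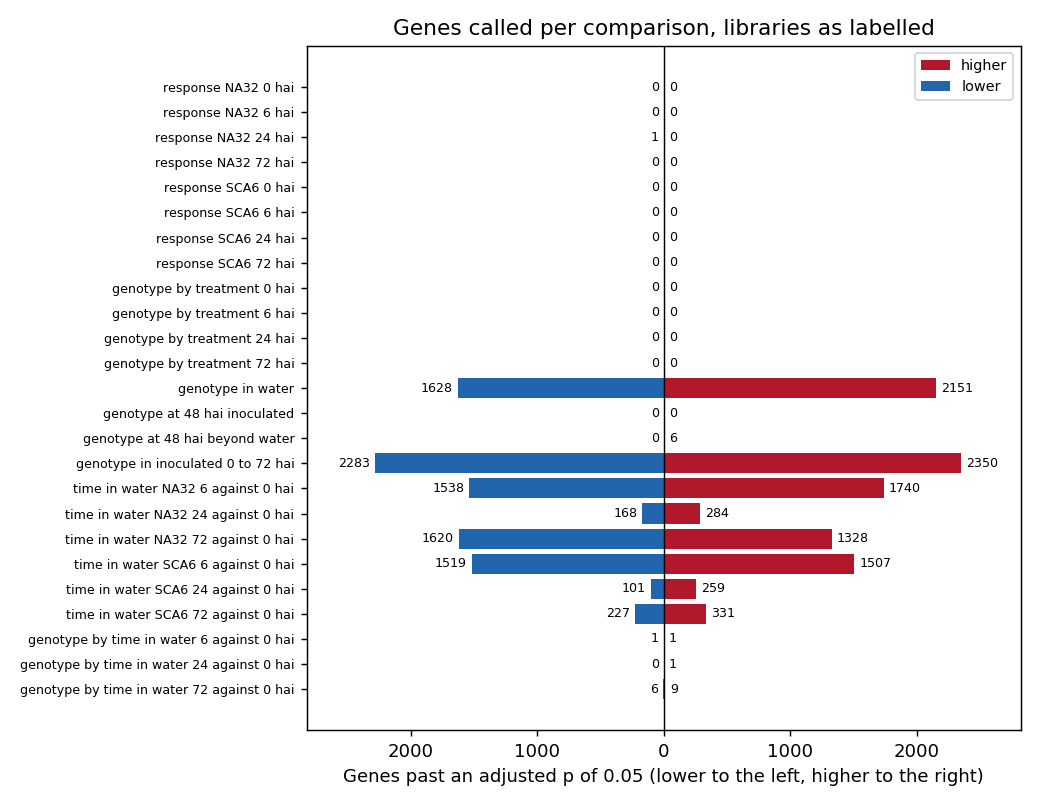
Number of genes past an adjusted p of 0.05 in each comparison with all libraries as labelled; bars to the right count genes that were higher and bars to the left genes that were lower. Differences between genotypes over 0 to 72 hai (3779 and 4633 genes) and between time points (360 to 3278 genes), from fits of 32 libraries, exceed the responses to inoculation (0 or 1 gene, fits of 16 libraries). At 48 hai the genotypes differed in 0 genes as labelled (8 libraries). Without the library labelled SCA6 inoculated 48 hai replicate 3, not drawn here, they differed in 1582 genes.

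The inoculated leaves of 0 to 72 hai showed the genotype difference again, with 4633 of 18105 genes, 2350 higher and 2283 lower in SCA6. Tc01v2_g014720 stood at 371 ± 66.6 CPM in SCA6 and 0.422 ± 0.921 CPM in NA32 (SD, n = 16 each). Tc03v2_g007520 stood at 10.5 ± 10.2 CPM in SCA6 and held 3 counts over the 16 NA32 libraries, a ratio of 1005 with a 95% counting interval of 344 to 4877. Tc01v2_g005720 stood at 19.2 ± 7.56 CPM in NA32 with 1 count over the 16 SCA6 libraries (ratio 5443, interval 977 to 215040). Tc05v2_g003080 stood at 6.36 ± 4.38 CPM in NA32 with 0 counts in SCA6, at least 588-fold lower (floor of 3 counts over the group). The adjusted p of these 4 genes was at most 5.97e-08. Of the genes tested in both comparisons, 1505 were higher in SCA6 in water and after inoculation (276 expected of independent lists), 1249 were lower in both (204 expected), and 0 went opposite ways. The fold changes of the genes called in water had the same sign after inoculation in 99.0% (r = 0.960 across genes, which are not independent replicates).

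At 48 hai, when only inoculated leaves were taken, the genotypes could be compared with each other but not with water. As labelled, 0 of 16520 genes passed with edgeR's quasi-likelihood test, with 2515 at an unadjusted p under 0.05, while limma voom called 4007 genes and DESeq2 711. Without the library labelled SCA6 inoculated 48 hai replicate 3, 1582 of 16834 genes passed, 773 higher and 809 lower in SCA6. Tc01v2_g014720 then stood at 404 ± 52.4 CPM in SCA6 (SD, n = 3) and 0.0820 ± 0.0723 CPM in NA32 (SD, n = 4), and Tc07v2_g011290 at 20.8 ± 7.02 CPM in SCA6 with 0 counts in NA32, at least 460-fold higher. In NA32, Tc01v2_g005720 stood at 25.5 ± 7.06 CPM and Tc02v2_g002750 at 15.1 ± 10.1 CPM (SD, n = 4 each), with 0 counts in the 3 SCA6 libraries, at least 573-fold and 366-fold lower in SCA6. The adjusted p of these 4 genes was at most 0.0102. The count of 1582 fell to 742, 482 and 507 without NA32 replicates 2, 3 and 4 and to 178 and 229 without SCA6 replicates 2 and 5, and rose to 3642 without NA32 replicate 5. Of the 1582 genes, 481 were also higher in SCA6 in water and 419 also lower (98.1 and 78.5 expected of independent lists), with 0 opposite, both comparisons taken without the libraries whose score opposed their label.

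Whether the difference at 48 hai went beyond the one in water was tested over all 72 libraries. As labelled, 6 genes passed, each with a less negative or more positive difference at 48 hai than in water, among them Tc01v2_g012150 and Tc01v2_g005720. In SCA6 at 48 hai these stood at 2.96 ± 5.90 and 5.50 ± 11 CPM (SD, n = 4), against 8.61 ± 1.34 and 25.5 ± 7.06 CPM in NA32 at that time (adjusted p = 0.00882 and 0.0379). Without the libraries whose score opposed their label 0 genes passed with edgeR's test, where 781 lay at an unadjusted p under 0.05 as labelled, and Tc01v2_g005720 was then at 0 counts in SCA6 at 48 hai. As labelled, DESeq2 called 35 genes and limma voom 2, both lower. With the replicate number as a block 0 genes passed. Left out 1 at a time, NA32 inoculated 48 hai replicates 2, 3 and 4 and the library labelled SCA6 inoculated 48 hai replicate 3 each took the count to 0, and NA32 inoculated 48 hai replicate 5 took it to 2. SCA6 inoculated 48 hai replicates 2, 4 and 5 took it to 17, 14 and 14, the library labelled NA32 water 6 hai replicate 3 took it to 15, and NA32 water 6 hai replicate 1 and NA32 water 24 hai replicate 2 took it to 3. NA32 water 6 hai replicate 2, SCA6 water 6 hai replicate 3, NA32 water 72 hai replicate 2 and SCA6 water 72 hai replicate 4 each took it to 2. The call of Tc01v2_g012150 was lost in the 4 refits with a count of 0, and its log2 difference of 8.21 was 1.08 without the library labelled SCA6 inoculated 48 hai replicate 3. The call of Tc01v2_g005720 was lost in those refits and in the 5 with a count of 2, and its log2 difference of 7.36 became -2.16 without the library labelled SCA6 inoculated 48 hai replicate 3.

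Water-sprayed leaves changed with time in both genotypes. Against 0 hai, 3278 genes changed in NA32 at 6 hai (1740 rose, 1538 fell) and 3026 in SCA6 (1507 rose, 1519 fell), of 18038 tested. The NA32 count was 2932 without the library labelled NA32 water 6 hai replicate 3. With all libraries, 1077 rose in both genotypes (145 expected of independent lists), 1015 fell in both (130 expected) and 1 went opposite ways. This overlap keeps that library of SCA6 pattern as NA32 and was not counted without it, so the agreement may rest in part on it. Tc04v2_g004020 was nearly silent at 0 hai and rose to 366 ± 287 CPM in NA32 (from 0.0990 ± 0.156 CPM) and to 184 ± 43.4 CPM in SCA6 (SD, n = 4 each), where 1 count at 0 hai gave a ratio of 12735 (interval 2285 to 503040). In NA32, Tc02v2_g013370 rose from 0.101 ± 0.203 to 70.1 ± 70.5 CPM, and Tc02v2_g013800 fell from 4.71 ± 1.60 CPM to 0 counts, at least 102-fold. Tc05v2_g026360 fell from 14.2 ± 26.6 CPM to 0 counts, but replicate 2 of the 0 hai group, at 54.2 CPM, carried that mean, and the other 3 libraries lay between 0.540 and 1.52 CPM. In SCA6, Tc03v2_g014310 rose from 0.169 ± 0.201 to 52.2 ± 7.22 CPM, while Tc02v2_g009010 fell from 120 ± 37.9 to 0.137 ± 0.140 CPM and Tc01v2_g027790 from 1156 ± 83.9 to 3.24 ± 2.12 CPM (SD, n = 4 each). The adjusted p of these 8 changes was at most 0.0109. The log2 fold changes of Tc04v2_g004020 and Tc02v2_g013370 in NA32, 11.75 and 9.36, were 11.11 and 8.43 without NA32 water 6 hai replicate 5, and 13.60 and 13.15 without NA32 water 0 hai replicates 4 and 5. In SCA6 those of Tc04v2_g004020 and Tc03v2_g014310, 13.04 and 8.19, were 14.52 and 9.18 without SCA6 water 0 hai replicate 4. That of Tc02v2_g009010, -9.51, was -10.26 without SCA6 water 6 hai replicate 2. The call of Tc05v2_g026360 was lost without NA32 water 0 hai replicate 2 (log2 fold change -6.87 in place of -10.84) and with limma voom (adjusted p = 0.162). Hours after spraying, the hour of the day and leaf age moved together here, and water-sprayed leaves have no unsprayed counterpart.

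At 24 hai fewer genes differed from 0 hai in water: 452 in NA32 (284 rose, 168 fell) and 360 in SCA6 (259 rose, 101 fell), of which 86 rose in both (4.08 expected) and 36 fell in both (0.941 expected). Over all 18038 genes the changes of NA32 and SCA6 at 24 hai correlated at r = 0.0455, against 0.706 at 6 hai and 0.362 at 72 hai (across genes, which are not independent replicates). The value at 6 hai keeps the library labelled NA32 water 6 hai replicate 3 as NA32. Tc07v2_g003720 fell in both genotypes, from 164 ± 34.5 to 11.6 ± 2.03 CPM in NA32 and from 124 ± 23.3 to 15.3 ± 5.62 CPM in SCA6 (SD, n = 4 each). In NA32, Tc09v2_g029900 rose from 0.198 ± 0.207 to 5.58 ± 1.70 CPM, Tc02v2_g030920 from 0 counts to 0.547 ± 0.376 CPM, at least 10.9-fold, and Tc06v2_g008870 fell from 168 ± 267 to 9.86 ± 10.4 CPM (SD, n = 4 each). In SCA6, Tc04v2_g004020 rose from 1 count over 4 libraries to 3.99 ± 2.14 CPM (ratio 290, interval 51.7 to 11508), Tc05v2_g007150 rose from 0.0904 ± 0.131 to 7.49 ± 5.81 CPM, and Tc03v2_g021470 fell from 13.9 ± 7.32 to 1.86 ± 0.308 CPM (SD, n = 4 each). The adjusted p of these 8 changes was at most 0.0374. In NA32 the count fell to 257, 223 and 174 without replicates 1, 4 and 5 of the 0 hai group and to 170 and 206 without replicates 2 and 5 of the 24 hai group. In SCA6 it fell to 198, 173 and 181 without replicates 2, 4 and 5 of the 0 hai group and to 207 and 148 without replicates 1 and 2 of the 24 hai group. The call of Tc02v2_g030920 was lost without any of the 8 libraries compared except 24 hai replicates 1 and 5, that of Tc05v2_g007150 except 24 hai replicates 3 and 4, and that of Tc03v2_g021470 except 0 hai replicate 5. The call of Tc06v2_g008870 was lost without replicate 2 of the 0 hai group or replicate 1, 2 or 5 of the 24 hai group, with log2 fold changes between -5.13 and -1.82 over all 8 refits. With the replicate number as a block these 4 genes also lost their calls (adjusted p = 0.0577, 0.0889, 0.0813 and 0.139 in the order given), as did Tc02v2_g030920 with all 72 libraries in the fit (adjusted p = 0.0512).

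At 72 hai the water-sprayed leaves of NA32 differed from 0 hai in 2948 genes (1328 rose, 1620 fell) and those of SCA6 in 558 (331 rose, 227 fell). Of these, 108 rose in both genotypes (24.4 expected of independent lists), 72 fell in both (20.4 expected) and 5 went opposite ways. In NA32, Tc04v2_g005140 fell from 381 ± 293 CPM to 2 counts over 4 libraries (ratio 12019, interval 3327 to 99247) and Tc06v2_g019760 from 145 ± 116 CPM to 1 count (ratio 9167, interval 1645 to 362130). Tc05v2_g027010 rose from 1 count to 5.60 ± 2.92 CPM (ratio 348, interval 62.0 to 13765), and Tc02v2_g030920 from 0 counts to 0.522 ± 0.139 CPM, at least 10.5-fold. In SCA6, Tc06v2_g017770 rose from 4.19 ± 1.90 to 172 ± 183 CPM and Tc06v2_g017780 from 9.77 ± 6.71 to 396 ± 461 CPM, while Tc06v2_g013480 fell from 4.56 ± 3.04 to 0.644 ± 0.468 CPM and Tc02v2_g009010 from 120 ± 37.9 to 19.4 ± 13.4 CPM (SD, n = 4 each). The adjusted p of these 8 changes was at most 0.0462. In NA32 the count fell to 1433 and 1481 without replicates 4 and 5 of the 0 hai group and to 1606, 1454 and 1117 without replicates 2, 3 and 5 of the 72 hai group. The call of Tc05v2_g027010 was lost without 0 hai replicate 4. In SCA6 the count was 937 without replicate 1 of the 0 hai group and 325, 152 and 172 without replicates 2, 4 and 5 of it. Replicate 2 of the 72 hai group, at 446 and 1085 CPM, carried the means of Tc06v2_g017770 and Tc06v2_g017780, and their log2 fold changes of 5.36 and 5.35 were 4.27 and 4.09 without it. The inoculated SCA6 leaves of 0 hai stood at 39.0 ± 39.1 and 74.0 ± 74.6 CPM (SD, n = 4 each) of these genes. The call of Tc06v2_g013480 was lost without any of the 8 libraries except 0 hai replicate 1, with the replicate block (adjusted p = 0.0760) and without the low-count filter (adjusted p = 0.0556).

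The change with time in water differed between the genotypes for few genes, 2 at 6 hai, 1 at 24 hai and 15 at 72 hai (9 with a more positive and 6 with a more negative change in SCA6). At 6 hai Tc02v2_g030920 went from 50.5 ± 8.27 to 2.16 ± 0.986 CPM in SCA6 and from 0 counts to 1.52 ± 1.66 CPM in NA32 (SD, n = 4 each; adjusted p = 0.000209). Tc02v2_g008620 went from 23.4 ± 1.86 to 48.7 ± 11 CPM in SCA6 and from 60.8 ± 4.87 to 55.5 ± 7.61 CPM in NA32 (log2 difference 1.19, adjusted p = 0.0370, or 0.151 without the library labelled NA32 water 6 hai replicate 3). At 24 hai Tc03v2_g023210 went from 112 ± 27.8 to 397 ± 71.6 CPM in SCA6 and from 224 ± 31.2 to 126 ± 34.7 CPM in NA32 (log2 difference 2.65, SE 0.40, adjusted p = 0.00769). At 72 hai Tc06v2_g017770 and Tc06v2_g017780, which rose in SCA6, stood in NA32 at 63.6 ± 52.0 and 94.4 ± 95.2 CPM at 0 hai and 37.6 ± 32.3 and 55.1 ± 48.4 CPM at 72 hai. Tc10v2_g000450 went from 15.3 ± 10.2 to 8.52 ± 2.55 CPM in SCA6 and from 2.85 ± 1.16 to 15.0 ± 2.76 CPM in NA32, and Tc05v2_g017280 from 8.66 ± 1.79 to 6.61 ± 1.90 and from 3.63 ± 0.466 to 12.8 ± 3.99 CPM (SD, n = 4 each). The adjusted p of these 4 genes was 0.0367.

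The 72 hai count of 15 rested on single libraries. It was 242 without SCA6 water 72 hai replicate 4, 152 without NA32 water 72 hai replicate 1 and 50 without SCA6 water 0 hai replicate 2, while NA32 water 0 hai replicates 4 and 5 moved it less. It was 1 without SCA6 water 0 hai replicate 5 or NA32 water 72 hai replicate 3. It was 0 without NA32 water 0 hai replicate 1 or 2, SCA6 water 0 hai replicate 1 or 4, NA32 water 72 hai replicate 2 or 5 or SCA6 water 72 hai replicate 1, 2 or 5. In all these 11 refits Tc06v2_g017770, Tc06v2_g017780, Tc10v2_g000450 and Tc05v2_g017280 lost their calls, and Tc10v2_g000450 also without NA32 water 0 hai replicate 5. At 6 hai the call of Tc02v2_g008620 was lost without replicate 2, 4 or 5 of either 0 hai group, NA32 6 hai replicate 3 or 5 or SCA6 6 hai replicate 2 or 4. Over the 16 refits its log2 difference lay between 1.03 and 1.29. The call was also lost with DESeq2 size factors, with either other filter, with the replicate block and with all 72 libraries (adjusted p between 0.0513 and 0.175). With any of the libraries that lost this call left out the count at 6 hai was 1, except NA32 6 hai replicate 5, and at 24 hai 2 genes passed without SCA6 water 0 hai replicate 2.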

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

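The tests on the 2 libraries of opposite genotype pattern, on the main axis within groups, on an uneven draw of leaves and on the slope at 0 hai were chosen after the result was seen; the counts over other splits, except that of genes at an unadjusted p with 2 surrogate variables, and the 0 hai profile test were chosen before. The fits with 2 surrogate variables, on which some of these counts over splits rest, were themselves chosen after the data were seen. Of 86 sets of 4 libraries examined for 1 library far from the others, 8 stood apart, where chance gives about 1 in 20 groups, or 4.3.

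The genotype score of the library labelled SCA6 inoculated 48 hai replicate 3, 0.0371 against 0.904 for the next, stood apart from its group by a gap of 0.943 of the group's range, and the library labelled NA32 water 6 hai replicate 3 had the opposite mismatch at 0.892. Reads of the genes seen in the labelled genotype, with at most 3 counts over the libraries of the other, numbered 0 in both, and those seen so in the other were present for 13 of 14 and 11 of 11 genes, as a wrong genotype label predicts, so a mislabelled sample may be the source. A mixture of the genotypes was argued against by an upper limit of 0.628% for the labelled genotype. An exchange of these 2 libraries was argued against by the library labelled SCA6 inoculated 48 hai replicate 3, whose correlation with NA32 48 hai libraries (0.964 ± 0.0144, SD, n = 4) exceeded that with NA32 6 hai libraries (0.868 ± 0.0508, SD, n = 7) by 0.0953; a first test decided nothing, with the library labelled NA32 water 6 hai replicate 3 at 0.935 ± 0.0378 (SD, n = 8) to SCA6 6 hai and 0.919 ± 0.0111 (SD, n = 3) to SCA6 48 hai. Which samples they are stays open, no biological explanation was tested, and over 2556 pairs the closest were the library labelled SCA6 inoculated 48 hai replicate 3 with NA32 inoculated 72 hai replicate 2 (4.60 times sampling noise) and the library labelled NA32 water 6 hai replicate 3 with SCA6 water 6 hai replicate 3 (6.37 times), against 7.40 for the closest pair of a group.

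In SCA6 at 24 hai 2311 of 17374 genes lay at an unadjusted p under 0.05, above 5% of them, with 0 called by edgeR. An uneven draw of leaves along the main axis within groups was not decided. With 2 surrogate variables 14.7% of genes lay at an unadjusted p under 0.05, but another split reached 2156 of 17374 genes in the same fit. Whether the surrogate variables took up the axis was not tested. The axis held 26.0% of the squared difference between the groups. Its scores were -5.97 ± 49.3 in inoculated and -49.3 ± 27.6 in water libraries (SD, n = 4 each, exact permutation test, two-sided, p = 0.229). Of the 35 splits of the 8 libraries, 2 gave as many genes (2311, highest other 2431), and the same was true of the calls with 2 surrogate variables (2 of 35; 119, highest other 190), DESeq2 (2 of 35; 426, highest other 531) and limma voom (3 of 35; 1299, highest other 2718), so chance is not excluded for these counts. Of 5 such counts only that of the genes at an unadjusted p under 0.05 with 2 surrogate variables was reached by no other split (1 of 35; 2560, highest other 2156), the smallest share that 35 splits allow. As that count was chosen after the others were seen, it does not exclude chance for the response. A difference between the treatment blocks already present at 0 hai was not decided. The 0 and 24 hai profiles correlated at -0.0273 across genes, which a share of 0.556 of the 1225 combinations of splits reached or exceeded, and over the 2311 genes the slope of the 0 hai difference on that of 24 hai was -0.0555, where splits of the 0 hai libraries had an SD of 0.346. Net of the 0 hai difference 1000 of 18559 genes lay at an unadjusted p under 0.05, against 1309 in the same fit of all 72 libraries without that step, and with the replicate block 1520 of 17374 did. A response to the pathogen, a difference between the blocks and chance in how the leaves fell into groups stay open.

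Libraries of a group differed along 1 main axis, which held 36.8% of the variance within groups, and 2965 of 18559 genes followed it with an absolute correlation above 0.7. Library size was argued against, with 1.51% of the axis scores accounted for within groups (r = 0.123, permutation p = 0.450; Spearman's rho 0.162, permutation p = 0.266; r = 0.0674 without the 2 libraries farthest from the median; 70 libraries), as was the share of counts in the 10 highest genes, with 1.04% (r = 0.102, permutation p = 0.478; rho 0.175, permutation p = 0.215; r = 0.0510 without 2 such libraries). A shared day or block marked by the replicate number was not decided. Deviations of same-numbered libraries correlated between -0.662 and 0.626, with means from -0.248 in SCA6 at 0 hai to 0.179 in NA32 at 6 hai. They showed no steady agreement, but 3 shared numbers in each pair of groups cannot exclude it. Over the 3 measures set against the axis, the adjusted p was 0.478 for both and 0.267 for the number of genes with a count (r = -0.237, permutation p = 0.0891; rho -0.195, permutation p = 0.149; r = -0.185 without 2 such libraries). Leaf age, light and the plant, on which the labels give nothing per library, stay open and no biological explanation was tested.

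Other libraries stood apart from the 3 others of their group by the gap to the nearest as a share of the group's range. On the first principal component these were NA32 inoculated 6 hai replicate 4 (-97.6 against -1.18, a share of 0.952) and NA32 inoculated 48 hai replicate 5 (7.69 against 85.9, a share of 0.917). In total counts they were NA32 inoculated 48 hai replicate 3 (22.1 against 16 M, a share of 0.923) and SCA6 inoculated 48 hai replicate 2 (44.6 against 17.2 M, a share of 0.893). The genotype score of SCA6 inoculated 72 hai replicate 3 was 0.885 against 0.919 (a share of 0.940), within the SCA6 libraries. In NA32 water-sprayed leaves the log2 CPM of Tc07v2_g011290 at 72 hai was 3.25 in replicate 5 against -2.50 (a share of 0.907), and that of Tc07v2_g004230 at 0 hai was 3.91 in replicate 1 against 3.39 (a share of 0.915).

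Differences between genotypes that passed a test of the difference itself were the changes with time in water of 2 genes at 6 hai, 1 at 24 hai and 15 at 72 hai, among them Tc02v2_g030920, Tc03v2_g023210 and Tc06v2_g017780, and the 6 genes whose genotype difference at 48 hai was less negative or more positive than the one in water, among them Tc01v2_g012150. These 6 were 0 without the library labelled SCA6 inoculated 48 hai replicate 3.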

How the results depend on the processing

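Chosen after the result was seen were the tests without the 2 libraries of opposite genotype pattern, those with 2 surrogate variables, and all tests of the changes with time and of genotype in inoculated leaves. Small changes were recovered less often than large ones, at the depth and replicate number of these libraries, neither of which was varied: on simulated 24 hai SCA6 libraries 4%, 22% and 94% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, on NA32 at 6 hai 0%, 4% and 54%, and on genotypes in water 16%, 70% and 98%. The genes were simulated independently of each other, without the shared axis that held 36.8% of the real variance within groups. These rates therefore hold for such simulated counts only. The other settings meant for gene lists were not run, as the IDs carried no names. Counts are of edgeR's quasi-likelihood test unless another tool is named, and where a count moved, the cause was not tested.

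The responses of NA32 at 6 hai were called for 5 genes by DESeq2, 3 with all 72 libraries and 1 net of 0 hai. At 24 hai they were 0 without the filter, with only the 8 libraries and net of 0 hai, 8 with limma voom, 43 with DESeq2, 7 with 2 surrogate variables and 4 with all 72 libraries. Those of SCA6 at 24 hai were 1299 with limma voom, 426 with DESeq2, 119 with 2 surrogate variables and 1 with only the 8 libraries, and at 72 hai 58 with DESeq2 and 166 with all 72 libraries. Genotype by treatment gave 4, 18 and 6 genes at 6, 24 and 72 hai with DESeq2, 1 at 6 and 72 hai with all 72 libraries, and 1 at 24 hai with limma voom and with 2 surrogate variables. Genotype counts at a fold of at least 2 were 1394 in water and 1511 in inoculated leaves. At 48 hai limma voom called 4007, DESeq2 711, all 72 libraries 224 and the fit without the library of opposite pattern 1582; beyond water limma voom called 2, DESeq2 35 and that fit 0. Tc01v2_g005720 beyond water (log2 7.36) reversed to -0.50 with limma voom and to -2.06 without both libraries, or -2.16 without the library labelled SCA6 inoculated 48 hai replicate 3; with 1 library left out it reached 8.30 at most.

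Changes in NA32 water leaves at 24 hai were 291 at a fold of at least 2, 4310 with limma voom and 1026 with DESeq2, and at 72 hai 8808 with limma voom. In SCA6 they were 1936 (fold of at least 2) and 7251 (limma voom) at 6 hai, 2030 (limma voom), 723 (DESeq2) and 573 (all 72 libraries) at 24 hai, and 344 (fold of at least 2), 3355 (limma voom), 1222 (DESeq2) and 1186 (all 72 libraries) at 72 hai. Their difference between genotypes at 6 hai was 1 gene with DESeq2 size factors, without the filter, with the stricter filter and without the library of opposite pattern, 26 with limma voom and 22 with DESeq2; at 24 hai limma voom called 730 and DESeq2 98, and at 72 hai limma voom called 1168, DESeq2 551 and all 72 libraries 125.

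Replicate numbers were not shown to pair the samples: the groups compared shared 3 numbers, and same-numbered libraries correlated between -0.662 and 0.626. With the replicate block the counts were 0 for NA32 at 24 hai, 0 for 48 hai beyond water, 359 for SCA6 at 72 hai in water and 1 for the genotype difference at 6 hai in water; the other 21 counts stayed within 1.5 times. The 1582 genes of 48 hai without the library of opposite pattern were 717 with this block, 3230 with DESeq2 and 5337 with limma voom.

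With 1 library left out in turn, the lowest and highest counts were 0 and 1 for NA32 at 24 hai, 0 and 76 for SCA6 at 24 hai, 0 and 1 for SCA6 at 72 hai, and 0 and 0 for the other responses. Genotype by treatment gave 0 and 2 at 24 hai, 0 and 1 at 72 hai, and 0 and 0 before. Genotype gave 3332 and 4231 in water, 4244 and 5108 in inoculated leaves, 0 and 1582 at 48 hai and 0 and 17 beyond water. Changes with time gave 2512 and 3288, 170 and 389, and 1117 and 2558 in NA32 at 6, 24 and 72 hai, and 2067 and 4163, 148 and 359, and 152 and 937 in SCA6; their difference gave 1 and 3, 1 and 2, and 0 and 242. Of 380 values of named genes under other settings, 354 kept direction and call, 24 lost the call and 2 reversed; of 676 with 1 library left out, 569 kept both, 106 lost the call and 1 reversed.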

Other observations

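The counts over other splits were chosen before their results were seen, except those of genes at an unadjusted p in NA32 at 0, 6 and 72 hai, in SCA6 at 0 and 6 hai, for genotype by treatment, for the change with time and for 48 hai beyond water, and the slopes on NA32 and on water; the neighbour tests and the comparisons across all groups were chosen after the data were seen. A set of genes marked the 6 hai leaves whatever the genotype or treatment. Of the time points, 6 hai alone does not lie whole days from 0 hai, so hour of the day and hours after spraying cannot be told apart here. With all libraries as labelled, Tc04v2_g004020 averaged between 184 and 366 CPM in the 4 groups of 6 hai and at most 5.94 CPM in the other 14 groups. Tc03v2_g014310 averaged 47.1 to 65.1 CPM at 6 hai and at most 4.06 CPM in the other groups. Tc01v2_g027790 went the other way, at 2.12 to 3.24 CPM in the groups of 6 hai and 303 to 1156 CPM in the others, and Tc07v2_g003720 averaged 0.123 to 0.463 CPM at 6 hai and 6.57 CPM or more elsewhere.

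Genes of the same genotype difference lay next to each other in ID order more often than random sets of their size. The 886 genes at least 2-fold higher in SCA6 in water, without the library of opposite pattern, held 124 adjacent pairs against 42.9 in random sets, and the 657 higher in NA32 held 77 against 23.6. The longest runs were Tc01v2_g030580 to Tc01v2_g030640 (7 genes, higher in SCA6) and Tc10v2_g004380 to Tc10v2_g004480 (5 genes, higher in NA32). Genes that rose or fell in SCA6 at 6 hai were adjacent too, 95 pairs against 52.8 and 93 against 50.8, so adjacency was not particular to the genotype difference (permutation p = 1e-04 for each of these 4 sets, the smallest that 10000 draws can give, adjusted 0.00012 over 5 sets). Among the 25 genes seen in 1 genotype, with at most 3 counts over the other, 1 pair was adjacent, against 0.0303 (permutation p = 0.03).

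The shift of the group mean after inoculation was largest against its splits in SCA6 at 24 hai (exact permutation test, one-sided, p = 0.0571, adjusted 0.457 over 8 shifts; the smallest p that 35 splits allow is 0.0286). Of 10 correlations between response profiles, across genes, the highest was 0.439 between SCA6 at 24 and at 72 hai (permutation of libraries, two-sided, p = 0.0751, adjusted 0.751), and that between NA32 and SCA6 at 24 hai was 0.289 (p = 0.223, adjusted 0.885 in the same permutation test).

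Other splits of the same libraries into groups of the same sizes were counted for each comparison, the real one included. For the genotype difference in water 1 of 100 splits gave as many genes (3779, highest other 520), or 1 of 100 without the library of opposite pattern (4082, highest other 2012). For that in inoculated leaves it was 1 of 100 (4633, highest other 144), so chance is excluded for these counts of calls. For 48 hai beyond water it was 1 of 40 (6, highest other 0). Those splits exchanged genotypes within a time, so the genotype difference itself entered the spread within their groups and the count decides nothing. That count of 6 rests on the library labelled SCA6 inoculated 48 hai replicate 3 and was 0 without it. For the genes at an unadjusted p under 0.05 in this comparison chance is not excluded (23 of 40, with 781 genes, highest other 2697). No other split gave as many genes (1 of 35) for the changes in water of NA32 at 6 hai (3278, highest other 247), 24 hai (452, highest other 1) and 72 hai (2948, highest other 0). The same held for SCA6 at 24 hai (360, highest other 3). That is the smallest share that 35 splits allow, these comparisons were chosen after seeing the data, and it was not adjusted over them. The NA32 count at 6 hai also keeps the library labelled NA32 water 6 hai replicate 3. These shares alone therefore do not exclude chance. The counts alone do not exclude it for SCA6 at 6 hai (2 of 35; 3026, highest other 4494) and 72 hai (2 of 35; 558, highest other 2968). These SCA6 splits were also set against the change in the separate NA32 libraries, without the library labelled NA32 water 6 hai replicate 3. Across genes, which are not independent replicates, the real split at 6 hai had a slope of 0.608 (highest other 0.406). That was 1 of 35, the smallest share that 35 splits allow, and at 72 hai it was 11 of 35 (0.303, highest other 0.676). As the slope was chosen after the counts were seen, it does not by itself exclude chance for the change at 6 hai. A first measure, the absolute correlation, ignores size and decided nothing (3 of 35 at 6 hai; 0.65, highest other 0.70). On principal component 2 the SCA6 water libraries lay between -7.71 and 20.6 at 0 hai and between 53.2 and 94.5 at 6 hai. The separate inoculated SCA6 libraries lay between -5.06 and 18.3 and between 57.5 and 93.4. These scores argue against chance for the SCA6 change at 6 hai along that component, while on component 1 the 2 times overlapped. For the difference between genotypes in the change with time, 2 of 100 splits gave as many calls at 6 hai (2, highest other 299). At 24 hai it was 1 of 100 (1, highest other 0) and at 72 hai 2 of 100 (15, highest other 98). These splits exchanged time points within a genotype, so the change with time itself entered the spread within their groups. Their counts therefore cannot decide whether chance gave these calls. For the genes at an unadjusted p under 0.05 chance is not excluded at 6 hai (51 of 100, with 769 genes, highest other 3935) or 24 hai (5 of 100, with 1845, highest other 2227). At 72 hai the same limit leaves it undecided (4 of 100, with 3001, highest other 4658). At 6 and 72 hai another split called several times the real count, which cannot be told apart from the change with time that these splits mix in.

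For the responses to inoculation and the genotype by treatment test chance is not excluded. In NA32 at 24 hai 5 of 35 splits gave as many genes (1, highest other 1143), or 2 of 35 with 2 surrogate variables (7, highest other 90). Where the real count was 0 every split gives as many, so the count of splits decides nothing. This holds for 35 of 35 splits in NA32 at 0 hai (0, highest other 0), 6 hai (0, highest other 0) and 72 hai (0, highest other 1), and in SCA6 at 0 hai (0, highest other 406), 6 hai (0, highest other 2578), 24 hai (0, highest other 94) and 72 hai (0, highest other 53). It also holds for 100 of 100 splits of the genotype by treatment test at 0 hai (0, highest other 6), 6 hai (0, highest other 8), 24 hai (0, highest other 1) and 72 hai (0, highest other 16), and for 35 of 35 of the genotypes at 48 hai (0, highest other 2952).

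Genes at an unadjusted p under 0.05 can be counted in these comparisons too. In NA32 as many came from 18 of 35 splits at 0 hai (544, highest other 1813), 28 of 35 at 6 hai (362, highest other 3273), 12 of 35 at 24 hai (1059, highest other 4255) and 12 of 35 at 72 hai (394, highest other 1554). In SCA6 as many came from 24 of 35 at 0 hai (439, highest other 3572), 24 of 35 at 6 hai (311, highest other 5785) and 4 of 35 at 72 hai (1992, highest other 2295). For genotype by treatment as many came from 65 of 100 at 0 hai (562, highest other 3340), 97 of 100 at 6 hai (209, highest other 3776), 21 of 100 at 24 hai (1204, highest other 3571) and 21 of 100 at 72 hai (1072, highest other 2581). For the genotypes at 48 hai as many came from 3 of 35 (2515, highest other 5503), and 2 of 35 splits gave as many calls without the library labelled SCA6 inoculated 48 hai replicate 3 (1582, highest other 2291), so these counts do not exclude chance. These splits were also set against the genotype difference in the separate water libraries, without that library and the one labelled NA32 water 6 hai replicate 3. The real split had a slope of 1.12 across genes (highest other 0.938), which was 1 of 35, the smallest share that 35 splits allow. The absolute correlation, which ignores size, gave 2 of 35 (0.752, highest other 0.752). As the slope was chosen after the counts were seen, it does not by itself exclude chance for the 48 hai difference. The genotype scores, from genes chosen for each library on the others, argue against chance for those genes. At 48 hai they were 0.0245 to 0.0569 in the NA32 libraries and 0.904 to 0.956 in the SCA6 libraries, replicate 3 (0.0371) left aside. Splits that called many genes where the real one called 0 or 1, up to 2952 at 48 hai, 2578 in SCA6 at 6 hai and 1143 in NA32 at 24 hai, point to a structure of the samples other than these groups, which was not traced on these splits.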
